A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

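Saturated transposon analysis in yeast was used. A MiniDs transposon was mobilised on 2% galactose for 18 to 20 days, cells were reseeded in 2% dextrose, and DNA next to the insertions was sequenced. The series holds 11 samples in 14 sequencing runs. The deposited tables give insertions per gene as counts and reads per gene as counts, which the values show to leave out the position with the most reads. In the deposited position files the score is 100 plus 10 per read, as read from the values. Per the labels the build was sacCer3; the aligner is not given in the sources used here. The counts were checked against the position files: 96.7 to 98.66% of 5913 genes had the same number of insertions per run. Of 6600 names, 687 had no match in the reference table and therefore no position.

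Runs of one sample were summed. The first WT sample had 2 runs of one pool and the first spt5Δ5 sample 3 pools. Both spt5-S1-15A libraries, which carry 2 strain numbers in the labels, shared 141620 positions. Other pairs of samples shared 9.66 to 18.4%, and 2 runs of the first WT sample 60.2%. The 2 were summed to 1 sample although the design had planned 2, and the version with 2 is an added alternative. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples. Mating type is a in all WT and spt5Δ5 samples and in 1 spt5ΔCTR sample and alpha in the others. The track lines of the position files hold a library number and a place on a sample sheet. Runs with the same difference between these were taken as 1 sequencing set, which gave 4 sets that the labels do not name. No set holds every group. The sets were used only as an added block.

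Genes with at least 10 insertions in at least 2 samples were tested (5077 genes; those left out hold 2.65% of insertions) with edgeR 4.0.16 (TMM, robust quasi-likelihood, 1 model over 4 genotypes) in R 4.3.3, at a Benjamini-Hochberg adjusted p of 0.05. Normalised insertions are TMM-scaled CPM, the share of a sample's insertions scaled to a common total. Gene lists were tested with camera (preset correlation 0.01, and estimated) and fry from limma 3.58.1, with 93 tests adjusted together. DESeq2 1.42.0 was run as an alternative. Bins of 500 bp needed at least 5 positions in 2 samples. Totals, essential control shares and centromere shares were compared by exact permutation tests, two-sided, in SciPy 1.17.1; intervals are Wilson 95% intervals and cover counting error only. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

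The tests, the lists, the alternatives first planned and the rule for named genes were set before the data were examined. The rule takes, for each comparison and direction, the 10 genes with the smallest p among those past the threshold whose groups do not overlap, or 3 where fewer pass, with 11 genes around SPT5 always and up to 4 members of each list; the text gives a selection of the last. Of the others, 1 gene that the rule names is not reported here, though the counts include it. For bins it takes 5 in each direction. Marker genes were label checks. The SPT5 map was described in 3 ways, all chosen after it was seen: first by windows picked by eye, then by the longest stretch without positions in each group, which for spt5ΔCTR fell outside the C-terminal end and showed nothing of the allele, and last by the final position of each library. The report gives the second for spt5Δ5 and the third for spt5ΔCTR.

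The centromere term adds the fitted trend over distance as an offset. Alternatives were other size factors, DESeq2, no filter, a replicate block, mating type, only the groups compared, distinct positions, first runs, reads, the centromere term, genes beyond 50 kb and each library left out. For the reads alternative, reads per gene were summed anew from the position files over genes with a position. Unlike the deposited values, these sums keep the position with the most reads. Alternatives added later were the 2 spt5-S1-15A libraries apart and that together with the replicate block. The sequencing set, thinning to equal totals and the lists with the centromere term were added later too. With the set as a block the 2 runs of the first WT sample entered apart. That 1 sample thus counts as 2 there, although its runs shared 60.2% of positions. Only 1 of the 3 spt5Δ5 libraries shares a set with WT. The pipeline was tested on simulated data with 50 genes changed at each of 2-fold and 4-fold in each direction, with 9, 5 and 8 false calls for spt5Δ5, spt5ΔCTR and spt5-S1-15A. The changed genes were drawn from those with a mean of at least 10 insertions per sample.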

Results

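Transposon insertions were mapped across the genome of budding yeast (Saccharomyces cerevisiae) strains that differ in SPT5, which encodes a conserved elongation factor of RNA polymerase II. The groups were wild type (WT, 3 libraries), spt5Δ5 (3 libraries), spt5ΔCTR, which lacks the C-terminal repeat region (3 libraries), and spt5-S1-15A, in which serines of those repeats are alanines (2 libraries). Per the labels all WT libraries came from 1 strain, while each mutant library has its own strain number. The spread within WT therefore holds no difference between strains. A trait of that WT strain would show in every comparison with WT. A gene in which insertions slow growth in one strain yields fewer distinct insertion positions there. Insertions in genes totalled 383763, 82992 and 70644 in the spt5Δ5 libraries and 101520, 152118 and 129378 in the spt5ΔCTR libraries. The spt5-S1-15A libraries held 91533 and 104464, and the WT libraries 232588, 103172 and 105979. The 2 spt5-S1-15A libraries shared 73.4% of the positions of the smaller one, against 18.4% at most in other pairs of samples. They were therefore summed and counted as 1 sample, a decision taken after the positions were seen. In the gene counts of spt5-S1-15A, a position held by both libraries counts 2 times. The 2 runs of the first WT sample shared 112571 positions, and those in genes count 2 times in its total as well. No replicates remain in spt5-S1-15A, and its tests borrow the spread of the other groups.

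The log10 of total insertions did not separate any mutant from WT (exact permutation tests, two-sided; p = 1 for spt5Δ5, 0.8 for spt5ΔCTR and 0.5 for spt5-S1-15A, 0.96 or more after adjustment for the first pair and 0.9 for the last). The smallest p possible was 0.1 with 3 libraries against 3 and 0.25 with 1 against 3. Across 28 essential control genes of RNA polymerase II and the proteasome, WT held 0.0349% ± 0.0110 of its insertions (SD, n = 3). The share was 0.0372% ± 0.0118 in spt5Δ5 (n = 3; exact permutation p = 0.6) and 0.0455% ± 0.0135 in spt5ΔCTR (n = 3; exact permutation p = 0.4). It was 0.0931% in spt5-S1-15A (exact permutation p = 0.25), with Wilson 95% intervals of 0.0722 to 0.111% and 0.0796 to 0.117% for its 2 libraries. The 6 tests gave an adjusted p of 0.9 or more. HIS3, which the strains lack, held no insertion in any library.

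Insertion positions within SPT5 itself (chromosome XIII, 247677 to 250868, sacCer3, 1063 codons) differed between the strains. All 3 spt5Δ5 libraries held 0 positions from 250251 to 250723 (codons 859 to 1016), where the WT libraries held 48, 22 and 20 and the spt5ΔCTR libraries 24, 23 and 26. The last spt5ΔCTR position lay at 250515 (codon 947), and beyond it the WT libraries held 41, 25 and 20 positions and the spt5-S1-15A libraries 33 and 35. In spt5Δ5, 3, 1 and 1 positions lay beyond it. Both descriptions were chosen after the map had been seen. Insertions in SPT5 as a whole were 2.73-fold fewer in spt5Δ5 than in WT (log2 fold change -1.45 ± 0.29, SE, n = 3 and 3; adjusted p = 0.00116), a call lost with a term for distance to the centromere (adjusted p = 0.0639) and with reads in place of insertions. YML009W-B, an open reading frame next to SPT5, had fewer insertions in spt5Δ5 (log2 fold change -3.75 ± 0.41; n = 3 and 3) and is read with the allele, not as a separate gene.

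**Figure D1:**
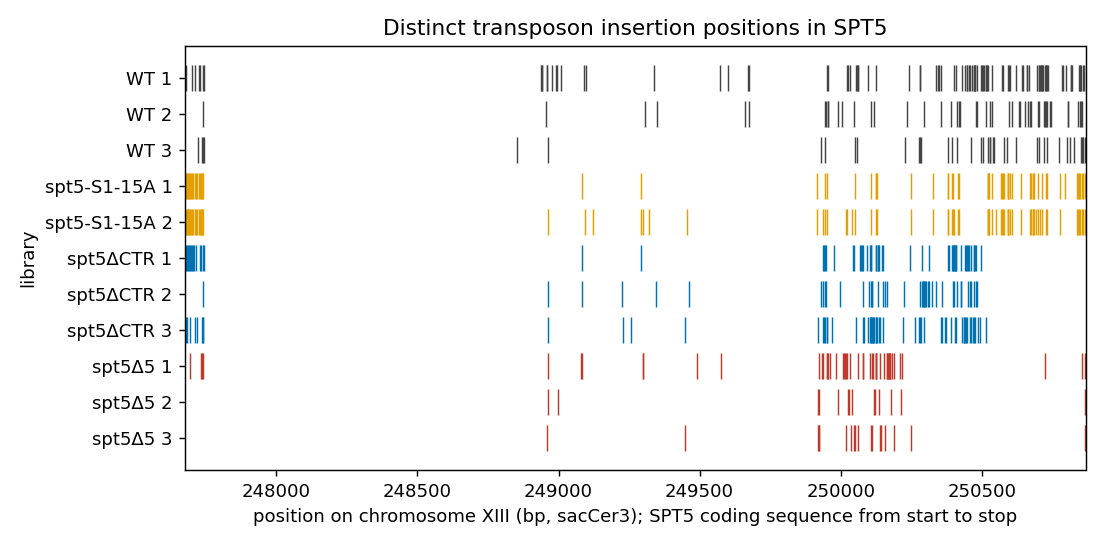
Distinct insertion positions in SPT5, 1 line per position, for each library; the x axis is the position on chromosome XIII in bp. The spt5Δ5 libraries lack positions from 250251 to 250723, and the spt5ΔCTR libraries lack positions after 250515.

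The comparison of spt5Δ5 with WT asked which genes became more or less tolerant of insertions in that mutant. GLK1, which encodes glucokinase, held 4.11-fold more (log2 fold change 2.04 ± 0.20, SE, n = 3 and 3; adjusted p = 4.70e-09), from 504 ± 94.3 normalised insertions (CPM) in WT to 2120 ± 402 (SD). The polyubiquitin gene UBI4 held 4.82-fold more, the peroxiredoxin gene TSA1 4.53-fold, and UBP2 and RUP1, a ubiquitin protease and its partner, 3.57-fold and 3.32-fold. LRE1 (3.01-fold), YPL247C (3.53-fold) and DYN1, the dynein heavy chain (2.86-fold), followed, and ENO1, an enolase, held 4.77-fold more, a value uncertain because its near-identical paralog ENO2 can share reads, as can the repeats within UBI4. PET8, which imports S-adenosylmethionine into mitochondria, held 6.78-fold fewer (log2 fold change -2.76 ± 0.26, n = 3 and 3; adjusted p = 2.62e-09), and RKR1, a ubiquitin ligase of ribosome quality control, 10.4-fold fewer. DEG1, a tRNA pseudouridine synthase, held 5.41-fold fewer, the sphingolipid phospholipase gene ISC1 4.98-fold, CDH1, an activator of the anaphase-promoting complex, 3.95-fold, and the mitochondrial ribosomal protein gene MRP4 3.56-fold. The coenzyme A carrier gene LEU5 held 3.20-fold fewer, the ribosome rescue gene DOM34 3.05-fold and the glucosyltransferase gene ALG6 2.94-fold. Of 5077 genes tested with edgeR, 595 passed (319 lower, 276 higher). Over all 5077 genes the 2 groups did not overlap in 29.2%, a separation chance gives to 10%.

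Position on the chromosome moved with this comparison. Positions within 2 kb of a centromere made up 1.65% ± 0.172 in spt5Δ5 and 2.65% ± 0.159 in WT (SD, n = 3 and 3; exact permutation p = 0.1, the smallest possible), and within 50 kb 24.2% ± 2.05 and 30.7% ± 1.23. Of the 292 lower genes with a position, 205 (70.2%) lay within 50 kb, against 15.0% of the genes tested. With a term for centromere distance 322 genes passed (106 lower, 216 higher), and 276 of them were among the 595. RKR1 (log2 fold change -3.55), PET8 (-1.92), CDH1 (-1.13), DEG1 (-1.42), MRP4 (-1.07), ISC1 (-2.03), LEU5 (-0.85) and ALG6 (-0.73) still passed, and DOM34 did not (adjusted p = 0.079). The count fell to 371 without spt5Δ5 replicate 2, and to 297, 364 and 346 without WT replicates 1, 2 and 3. DESeq2 called 312 genes, and reads per gene gave 35, with PET8, CDH1, GLK1, UBI4, LRE1, UBP2, YPL247C and DYN1 among the named genes that passed.

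**Figure D2:**
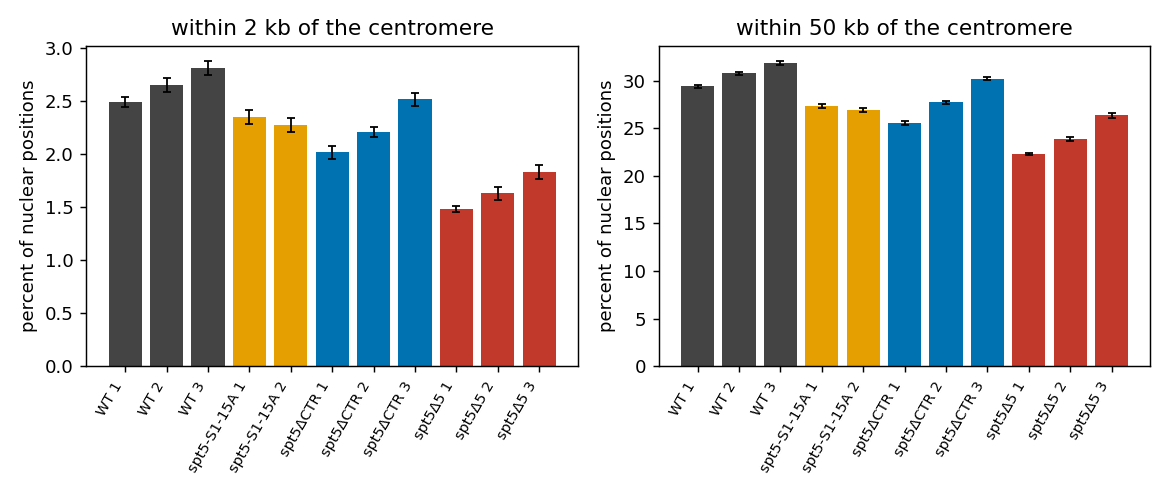
Percent of nuclear insertion positions within 2 kb (left) and within 50 kb (right) of a centromere, 1 bar per library; error bars are Wilson 95% intervals, which cover counting error only. The spt5Δ5 libraries, at 1.49 to 1.83% within 2 kb, lie below all 3 WT libraries.

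Genes of the Paf1 complex, an elongation factor complex that travels with RNA polymerase II, went in different directions in spt5Δ5. RTF1 held 7.73-fold fewer insertions (log2 fold change -2.95 ± 0.66, n = 3 and 3; adjusted p = 0.0022), with 6, 0 and 0 insertions against 26, 7 and 6 in WT, and no longer passed with DESeq2, reads per gene (adjusted p = 0.333) or the sequencing set as a block (0.0703). CTR9 held 4.22-fold more (log2 fold change 2.08 ± 0.52; adjusted p = 0.0118), but its call was lost without spt5ΔCTR replicate 1 (adjusted p = 0.0593), without WT replicate 1 (0.0925) and with the centromere term (0.053). CDC73 (log2 fold change 0.17) and LEO1 (0.49) did not pass, and PAF1 held too few insertions to be tested, as did BUR2 and GLC7. Neither SPT4, the partner of SPT5 (log2 fold change -1.49 ± 0.97; adjusted p = 0.401), nor SGV1, the kinase of the repeats (0.68 ± 0.36; adjusted p = 0.255), passed. REF2, a subunit of the phosphatase module of the 3-prime end machinery, held 2.15-fold more (adjusted p = 0.0185), a call lost without spt5Δ5 replicate 1 (0.12) or 2 (0.0633), without WT replicate 2 (0.111) and with the centromere term (0.0634). SWD2, an essential subunit of that module and of the COMPASS histone methyltransferase (chromosome XI, 404102 to 405091), held 38, 10 and 12 insertions against 1, 3 and 1 in WT (log2 fold change 3.26 ± 0.61, n = 3 and 3).

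Among the 31 gene lists fixed before the data were examined, camera called 3 in spt5Δ5. The histone chaperone genes HIR, CAF-1 and Asf1 shifted up (9 tested, 3 higher; adjusted p = 0.00738, but adjusted p = 0.708 with an estimated correlation). RTT106 was among them (log2 fold change 0.92 ± 0.24), a call lost without WT replicate 1 (adjusted p = 0.0821). Genes of Ccr4-Not, which shortens mRNA tails, shifted up (8 tested, 3 higher; adjusted p = 0.0146; adjusted p = 0.739 with an estimated correlation), with NOT3 at 1.63 ± 0.29 and MOT2 at 1.51 ± 0.33. Mitochondrial respiration genes shifted down (14 tested, 2 lower; adjusted p = 0.0363; adjusted p = 0.708 with an estimated correlation), with COQ1 at -1.71 ± 0.26, a call lost with the centromere term (adjusted p = 0.0503). Over all lists 21 members passed lower and 28 higher, and 25 and 33 when adjusted over the list alone. Members that passed included the chromatin remodeler gene CHD1 (1.58 ± 0.27), the silencing gene SIR3 (1.34 ± 0.31), the cyclic AMP phosphodiesterase gene PDE2 (1.87 ± 0.46), the Glc7 regulator gene SHP1 (1.89 ± 0.40), the Mediator kinase module gene SSN2 (1.13 ± 0.25), the SAGA gene SPT8 (-1.43 ± 0.28) and NHP6A, a high-mobility group protein gene (-2.28 ± 0.60). The other 28 lists had a camera adjusted p of 0.121 to 0.989, and fry called none by direction (adjusted p from 0.116), while its mixed test, for change in either direction, called 15 lists here, 4 in spt5ΔCTR and 2 in spt5-S1-15A. No list passed without spt5Δ5 replicate 3 (adjusted p = 0.0865 for the histone chaperones and 0.0919 for the other 2). Mitochondrial respiration was also lost without spt5Δ5 replicate 2 (0.0840) and WT replicate 1 (0.0930) or 2 (0.107). With the sequencing set as a block the 3 lists had an adjusted p of 0.522, 0.221 and 0.756. With the centromere term the camera adjusted p was 0.0213, 0.0262 and 0.0250 at the preset correlation.

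The comparison of spt5ΔCTR with WT asked what the loss of the repeat region alone changes. GLK1 held 3.35-fold more insertions (log2 fold change 1.74 ± 0.20, SE, n = 3 and 3; adjusted p = 2.07e-07), TSA1 3.72-fold more, IMP2', a transcriptional activator gene, 3.62-fold more and DYN1 2.34-fold more. The membrane stress protein gene HSP12 (3.20-fold), the iron-sulfur scaffold gene ISU1 (5.52-fold), SWD2 (log2 fold change 3.03 ± 0.63), UBI4 (2.99-fold) and ICY2 (3.29 ± 0.69) were also higher. MRP4, which encodes a mitochondrial ribosomal protein, held 5.54-fold fewer (log2 fold change -2.47 ± 0.27; adjusted p = 1.10e-07), PET8 4.79-fold, the coenzyme Q genes COQ6 4.48-fold and COQ1 3.47-fold, and LEU5 3.63-fold. MAC1, a copper-sensing transcription factor gene (3.76-fold), the ergosterol gene ERG4 (3.22-fold), the cyclin gene PHO80 (3.05-fold), ALG6 (2.52-fold) and the ubiquitin ligase gene UBR2 (2.29-fold) were lower as well. SWD2 held 7, 11 and 21 insertions against 1, 3 and 1 in WT, and ICY2 18, 13 and 13 against 4, 1 and 0. edgeR called 103 of 5077 genes (65 lower, 38 higher), and camera called the mitochondrial respiration list down (14 tested, 1 lower, 3 when adjusted over the list alone; adjusted p = 0.000802; adjusted p = 0.708 with an estimated correlation). Over the 31 lists 1 member passed lower and 2 higher, and 4 and 3 when adjusted over the list alone. The other 30 lists had an adjusted p of 0.0952 to 0.929, and no gene of the Paf1 complex passed (CTR9, log2 fold change 1.14; RTF1, -1.18).

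Within 50 kb of a centromere lay 40 of the 61 lower genes with a position (65.6%), and with the centromere term 78 genes passed (45 lower, 33 higher), 73 of them among the 103. MRP4 (-2.11), PET8 (-1.85), COQ6 (-2.22), COQ1 (-1.42), MAC1 (-1.83), LEU5 (-1.46) and UBR2 (-1.07) still passed. Without single libraries the count was 29 (spt5ΔCTR replicate 2), 62 (spt5ΔCTR replicate 3), 41, 53 and 40 (WT replicates 1, 2 and 3). SWD2 no longer passed without spt5ΔCTR replicate 3 (adjusted p = 0.0667) or WT replicate 1 (0.139), and HSP12 (0.0696 and 0.154) and ISU1 (0.0805 and 0.0638) without spt5ΔCTR replicate 2 or WT replicate 1. UBI4 no longer passed without WT replicate 1 (0.0638), nor ICY2 without WT replicate 2 (0.0531) or 3 (0.0548). Other counts were 42 by DESeq2, 22 with mating type as a term, 60 with the sequencing set as a block and 7 by reads per gene. In the fit within 1 sequencing set, WT was only 1 run of its first sample, so its count is not read as a result.

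**Figure D3:**
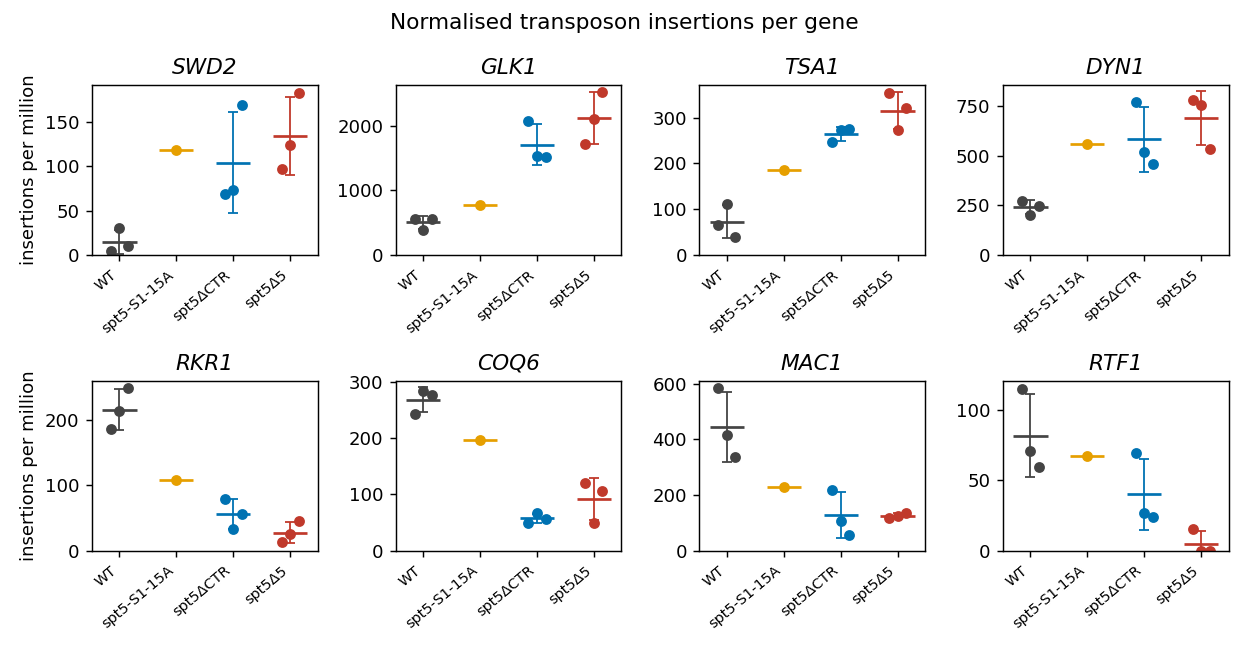
Normalised insertions (CPM) for 8 named genes, 1 point per sample with the group mean and SD (spt5-S1-15A is 1 summed sample). SWD2 rose from 14.9 in WT to 135 in spt5Δ5 and 104 in spt5ΔCTR, and RKR1 fell from 215 in WT to 27.8 in spt5Δ5.

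The comparison of spt5-S1-15A with WT asked which genes respond to loss of the repeats' phosphorylated serines. edgeR called 1 gene: YLR202C, an open reading frame without a position in the reference used, held 3.41-fold more insertions (log2 fold change 1.77 ± 0.33, SE, n = 1 and 3; adjusted p = 0.0209). The next genes did not pass: SWD2 (log2 fold change 3.22 ± 0.72; 9 and 14 insertions; adjusted p = 0.0766), the phosphatase gene PPZ2 (1.57 ± 0.34; 0.0573), the sorting receptor gene MRL1 (-2.08 ± 0.44; 0.0573), the pH sensor gene RIM21 (-2.17 ± 0.49; 0.0766) and the carbonic anhydrase gene NCE103 (-2.11 ± 0.48; 0.0766). With the centromere term 4 genes passed, SWD2, MRL1 and RIM21 among them (0.0383 each). Without that term the main edgeR fit and DESeq2 called no gene lower. Other edgeR fits without it did, among them those without spt5ΔCTR replicate 1 or 3, without spt5Δ5 replicate 1 and with no low-count filter. With the term edgeR called 2 lower, and with only the groups compared 105. On simulated counts the test recovered 92% of genes with 4-fold more and 58% with 4-fold fewer insertions, but 24% and 10% at 2-fold. The simulation drew spt5-S1-15A without positions that count 2 times, and changed only genes with at least 10 insertions on average. Recovery in the real summed sample, or in sparser genes, may therefore differ. The only list called was RNA polymerase II core subunits, an essential control with 2 genes tested (both higher when adjusted over the list alone, neither over all genes; median log2 fold change 1.57; adjusted p = 0.0388; adjusted p = 0.708 with an estimated correlation). The list was lost without spt5Δ5 replicate 2 or 3, spt5ΔCTR replicate 2, spt5-S1-15A replicate 2 or WT replicate 2 or 3 (0 lists each; adjusted p = 0.0501 to 0.162), and 2 lists passed without spt5-S1-15A replicate 1. The other 30 lists had an adjusted p of 0.0692 to 0.973. Over the 31 lists no member passed over all genes, and 3 lower and 10 higher did when adjusted over the list alone.

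The call of YLR202C was lost without either spt5-S1-15A library (adjusted p = 0.0745 and 0.0835) and without WT replicates 1, 2 and 3 (0.0531, 0.109 and 0.16). The count was 0 without either spt5-S1-15A library or WT replicate 1 or 2, 31 without spt5ΔCTR replicate 1, 6 without spt5Δ5 replicate 1 and 5 without spt5ΔCTR replicate 3. Counted as separate samples, as first planned, the 2 libraries gave 94 genes.

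The comparison of spt5ΔCTR with spt5-S1-15A set removal of the repeats against loss of their serines. Insertions in MRP4 were 3.92-fold fewer in spt5ΔCTR (log2 fold change -1.97 ± 0.34, SE, n = 3 and 1; adjusted p = 0.00565), and YLR202C (2.96-fold fewer), GYL1, a regulator of vesicle transport (3.09-fold), IRC19 (2, 2 and 3 insertions against 12 and 17) and YML009W-B, next to SPT5 (4.11-fold), passed as well. With all groups in the model edgeR called no gene higher, 635 genes had an unadjusted p under 0.05 in either direction, and DESeq2 called 0. GLK1 (1.14 ± 0.28, adjusted p = 0.0678) and YLR225C and BMT6, with 1 insertion each in spt5-S1-15A, did not pass there. GLK1 did in 9 of 26 other settings, among them the centromere term (0.0336) and the sequencing set as a block. With that block the comparison rests on spt5ΔCTR replicate 1, the only library that shares a set with spt5-S1-15A. The count was 0 without spt5ΔCTR replicate 2, 1 without either spt5-S1-15A library, 2 without spt5Δ5 replicate 2, spt5ΔCTR replicate 3 or any single WT library, 24 and 19 without spt5Δ5 replicates 1 and 3, and 33 without spt5ΔCTR replicate 1. Genes called higher were 3, 2 and 10 of these last 3 counts, 1 with the centromere term and 1 without genes near centromeres. They were 4 with no low-count filter, 7 with the sequencing set as a block, 41 with the spt5-S1-15A libraries apart and 19 with these apart and a replicate block. MRP4 was lost without spt5ΔCTR replicate 2 (0.161) or spt5-S1-15A replicate 2 (0.0579), YML009W-B without spt5ΔCTR replicate 2 (0.161) or spt5-S1-15A replicate 1 (0.0854), and YLR202C, GYL1 and IRC19 without any of 8 libraries (0.0546 to 0.177).

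The comparison of spt5Δ5 with spt5ΔCTR asked how the mutants with missing SPT5 sequence differ from each other. NOT3, a subunit of Ccr4-Not, held 3.35-fold more insertions in spt5Δ5 (log2 fold change 1.74 ± 0.30, SE, n = 3 and 3; adjusted p = 0.00135), PCS60 2.29-fold more, the arginine synthesis gene CPA1 2.72-fold more and SST2, a regulator of pheromone signalling, 2.96-fold more. LRE1, UBP2, MSC3, BST1 and GIS3 held 1.77-fold to 2.45-fold more. SCS3, a lipid metabolism gene, held 3.78-fold fewer (log2 fold change -1.92 ± 0.27; adjusted p = 7.02e-05), MHF1, a DNA repair gene, 5.45-fold fewer, FAR7 5.63-fold and RNQ1, a prion protein gene, 3.43-fold. DEG1, MET14, HTZ1, which encodes the histone variant H2A.Z, MIT1 and PUF4 held 2.16-fold to 3.81-fold fewer. SPT5 itself (log2 fold change -1.43 ± 0.30; adjusted p = 0.0158) and YML009W-B (-2.20 ± 0.49; 0.018) were lower and are read with the alleles; SPT5 was lost without spt5Δ5 replicate 1 (0.0734) or 2 (0.0875) and with the centromere term (0.102), and YML009W-B without spt5Δ5 replicate 1 (0.238) or 2 (0.067) or spt5ΔCTR replicate 3 (0.0911). edgeR called 68 genes (38 lower, 30 higher), DESeq2 26, and the count was 24 with the centromere term (DEG1, MET14, HTZ1, MIT1, PUF4 and SST2 no longer passed), 7 with mating type as a term and 6 with the sequencing set as a block.

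The count of 68 was 124, 7 and 28 without spt5Δ5 replicates 1, 2 and 3, 111, 14 and 33 without spt5ΔCTR replicates 1, 2 and 3, and 42 and 38 without WT replicates 2 and 3. NOT3, SCS3, MHF1, FAR7, RNQ1 and DEG1 passed without any single library. MET14 was lost without spt5ΔCTR replicate 2 (adjusted p = 0.0933), as were PCS60 (0.108), CPA1 (0.0935), LRE1 (0.0862), UBP2 (0.0933), MSC3 (0.0935), SST2 (0.155), GIS3 (0.123), MIT1 (0.0933) and PUF4 (0.0592). Without spt5Δ5 replicate 2, HTZ1 (0.067), MIT1 (0.0621), PUF4 (0.0816), PCS60 (0.0621), CPA1 (0.0894), LRE1 (0.0621), UBP2 (0.0628), MSC3 (0.067), BST1 (0.067), SST2 (0.111) and GIS3 (0.0628) were lost. Without spt5Δ5 replicate 1, HTZ1 (0.0574), PUF4 (0.0522) and MSC3 (0.0752) were lost. Without spt5Δ5 replicate 3, MIT1 (0.0506), UBP2 (0.0756), BST1 (0.0593), SST2 (0.078) and GIS3 (0.0972) were lost. Without spt5ΔCTR replicate 3, HTZ1 (0.0516), MIT1 (0.0557), CPA1 (0.0516), MSC3 (0.0528) and BST1 (0.11) were lost, and SST2 also without spt5ΔCTR replicate 1 (0.0614).

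Over the mean of the mutants, SWD2 held more insertions than in WT (log2 fold change 3.17 ± 0.56, SE, n = 7 and 3; adjusted p = 0.000408; 1, 3 and 1 insertions in WT), GLK1 2.76-fold, TSA1 3.53-fold, DYN1 2.48-fold, IMP2' 2.85-fold and YPR117W 1.98-fold more. RUP1 (2.17-fold) and GRE1 (2.94-fold) passed but not without WT replicate 1 (adjusted p = 0.0601 and 0.0996), and MAM3 (1.86-fold) not without WT replicate 3 (0.052). PET8 held 4.14-fold fewer (log2 fold change -2.05 ± 0.20; adjusted p = 5.77e-09), RKR1 4.28-fold, MAC1 3.05-fold, MRP4 3.03-fold, LEU5 3.01-fold, SNF8, an ESCRT gene, 2.98-fold, CDH1 2.62-fold, ALG6 2.24-fold, UBR2 2.00-fold and RMD1 1.94-fold. edgeR called 208 genes (135 lower, 73 higher), and 105 (48 lower, 57 higher; 87 shared) with the centromere term, under which RMD1 was lost (adjusted p = 0.289). The count was 69, 94 and 81 without WT replicates 1, 2 and 3, 82 by DESeq2, 34 with mating type as a term and 9 by reads per gene.

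Many of the genes called in spt5ΔCTR were also called in spt5Δ5. Both called 84 genes, 53 lower, such as PET8, MRP4 and RKR1, and 31 higher, such as GLK1, TSA1 and SWD2. Independent calls would share 4.08 and 2.07, a figure that leaves out the WT libraries common to both comparisons. In 20 simulations of unchanged groups sharing the WT libraries at most 1 gene was shared. Unchanged groups yield few calls to share, so that count is no reference for lists of 595 and 103. Neither figure holds the centromere trend seen in both mutants. Across genes, which are not independent replicates, the log2 fold changes had r = 0.65, against 0.49 on average in the simulations. For spt5-S1-15A, r was 0.34 with spt5Δ5 and 0.38 with spt5ΔCTR, against 0.36 and 0.35 in the simulations. The covariances, however, were 0.169 and 0.156, against 0.0855 and 0.0831 on average in the simulations and 0.0906 and 0.0889 at most. The single spt5-S1-15A call, YLR202C, was not called in either deletion, and a list of 1 says nothing about sharing. The shared count was 50 with the centromere term, 33 by DESeq2, 19 with mating type as a term and 25 to 87 without single libraries, lowest without spt5ΔCTR replicate 2.

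**Figure D4:**
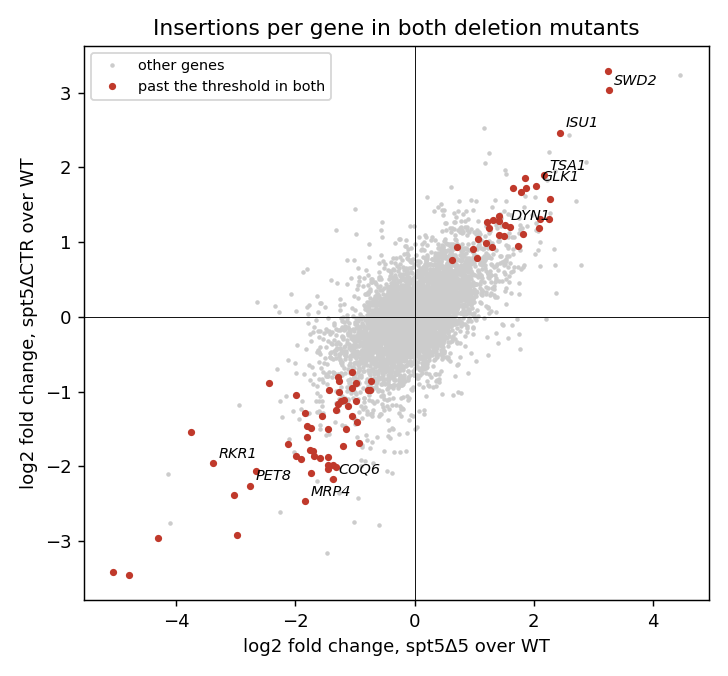
Log2 fold change of insertions per gene in spt5ΔCTR over WT (y axis) against spt5Δ5 over WT (x axis), 1 point per gene; red points are the 84 genes past the threshold in both. PET8 and MRP4 lie low in both and GLK1 and SWD2 high in both.

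In bins of 500 bp, insertions were counted along the genome outside gene models as well. In spt5Δ5 a bin in GLK1 (chromosome III, 51001 to 51500) had a log2 fold change of 2.46 ± 0.24 (SE, n = 3 and 3), bins in EAP1, a translation regulator gene, 3.36, in the pyruvate decarboxylase gene PDC1 3.66, in the kinase gene YAK1 3.05 and in IMP2' 2.06. Lower bins lay in PET8 (-2.59), beside the centromere of chromosome XIV (-1.96), in YIL001W (-1.75), in DEG1 (-2.72) and at ERP6 and ERG26 (-1.56). In spt5ΔCTR the bins in GLK1 (2.02 and 1.87), IMP2' (2.12), PDC1 (3.06) and MHF1 (1.39) were higher, and those in PET8 (-2.41), MRP4 (-2.53), STP22 (-2.17), ALG6 (-1.43) and HSE1 (-1.57) lower. In spt5-S1-15A bins in RRD1 (1.85), RAD26 (2.55), PPZ2 (2.97), PHA2 (2.73) and RPS9B (1.62) were higher, and bins in GLC3 (-2.41) and outside genes on chromosomes II (-4.27), IV (-2.45) and IX (-3.28) lower; the bin on chromosome XVI (-1.50; adjusted p = 0.061) did not pass. Of 18828 bins, edgeR called 1047 in spt5Δ5 (656 lower, 507 of them within 50 kb of a centromere, and 391 higher), 49 in spt5ΔCTR and 17 in spt5-S1-15A. Without single libraries these counts ranged from 448 (WT replicate 3) to 1205 (spt5ΔCTR replicate 1), from 18 (spt5ΔCTR replicate 2) to 67 (spt5Δ5 replicate 1) and from 0 (WT replicate 3) to 29 (spt5ΔCTR replicate 1). For spt5Δ5 the bins numbered 684 and 626 without spt5Δ5 replicates 1 and 2 and 573 and 527 without WT replicates 1 and 2. For spt5ΔCTR they numbered 32 without spt5ΔCTR replicate 3 and 19, 31 and 18 without WT replicates 1, 2 and 3. For spt5-S1-15A they numbered 9 without spt5Δ5 replicate 2, 8 and 9 without the 2 spt5-S1-15A libraries and 5 and 1 without WT replicates 1 and 2.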

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

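All tests in this part were chosen after the result was seen. The 2 spt5-S1-15A libraries shared 73.358% of the positions of the smaller library, as seen in the position files. The gene counts hold the same positions and were summed over both libraries, so a shared position counts 2 times there. Positions that every library hits are argued against, since no other pair of samples shared more than 18.379%. Carry-over stays open. The only other library of the sequencing set, spt5ΔCTR replicate 1, shared 10.967% with spt5-S1-15A replicate 1, below the 16.393% of a library of another set, but 1 library excludes nothing and does not test carry-over between the 2 alone. That both hold 1 pool of insertions stays open. Their gene counts varied 0.428 times as much as counting error alone would give. Shared positions lower that ratio by themselves, so it decides nothing. Log2 read numbers at the shared positions had r = 0.802. That value was 0.544 between the 2 runs of the first WT sample and 0.302 at most in other pairs of samples. These values go with 1 pool, but carry-over between the 2 libraries could not be told apart from it. In another set, WT replicate 2 and the first run of spt5Δ5 replicate 1 shared 17.594%, with r = -0.035 for their log2 read numbers. WT replicate 3 and that same run shared 14.235%, with r = 0.222. Whether carry-over lies behind this was not tested, and these libraries enter the comparison of spt5Δ5 with WT. No biological explanation was tested, and the labels, which give 2 strain numbers, leave open at which step the libraries came to share positions.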

How the results depend on the processing

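The alternatives with the 2 spt5-S1-15A libraries apart, alone or with the replicate block, the sequencing set as a block or a single set, thinned totals, and the lists with the centromere term were chosen after the data were seen; the others were planned. Of the values of named genes under the alternatives, 4356 kept their side of the threshold, 790 kept direction but no longer passed and 70 newly passed. Among the 4356, direction was compared only where the gene passed. A further 3 that passed in the main fit or under the alternative reversed direction. Those were RRP6 in spt5Δ5 with the centromere term (0.20; RRP6 lies 1.45 kb from a centromere), SPT5 in spt5Δ5 against spt5ΔCTR with reads per gene (0.35) and MAM3 over all mutants with reads per gene (-0.66). The cause was not tested for the last pair, nor for the counts below unless said.

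Counts of genes are given in the order spt5Δ5, spt5ΔCTR and spt5-S1-15A against WT, spt5ΔCTR against spt5-S1-15A, spt5Δ5 against spt5ΔCTR, and all mutants against WT, where the reported counts were 595, 103, 1, 5, 68 and 208. The DESeq2 test gave 312, 42, 0, 0, 26 and 82, and reads per gene 35, 7, 2, 3, 0 and 9. The centromere term gave 322, 78, 4, 6, 24 and 105, and genes beyond 50 kb, fewer of which were tested, 273, 41, 1, 1, 32 and 63. A replicate block gave 589, 110 and 85 for the comparisons without spt5-S1-15A. It was not run alone for the others, since the summed sample has no replicate number. With the block and both spt5-S1-15A libraries apart, changed together, they gave 68, 56 and 337. Replicate numbers do not pair the samples. Mating type as a term, which differs between groups, gave 581, 22, 0, 2, 7 and 34. ERG4, ALG6, DYN1, HSP12, ISU1 and ICY2 were among the genes no longer called in spt5ΔCTR then.

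Only the groups compared gave 169 genes in spt5-S1-15A, 0 in spt5ΔCTR against spt5-S1-15A and 17 in spt5Δ5 against spt5ΔCTR. With DESeq2 size factors in edgeR, spt5ΔCTR against spt5-S1-15A gave 11 genes, and with distinct positions over runs 1. No low-count filter gave 7 in spt5-S1-15A and 23 in spt5ΔCTR against it, and the first run of each sample gave 0 and 3. With both spt5-S1-15A libraries apart, spt5-S1-15A gave 94, spt5ΔCTR against it 107 and all mutants 331, where gene counts of the 2 libraries varied 0.428 times as much as counting error alone would give. The sequencing set as a block gave 469, 60, 0, 17, 6 and 94, and within 1 set spt5ΔCTR gave 61. In that fit within 1 set, WT was only 1 run of its first sample. It had no replicate there, so its count is not read as a result. Thinned totals gave 413, 52, 3 for spt5ΔCTR against spt5-S1-15A, 85 for spt5Δ5 against spt5ΔCTR and 123 for all mutants.

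For spt5-S1-15A, 17 bins became 10 at 1000 bp, 358 with both libraries apart and 283 with these and a replicate block together. Lists called by camera (3, 1 and 1) became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 by fry's directional test. The mixed test of fry called 15, 4 and 2. With the centromere term and the preset correlation, the lists first called in spt5Δ5 still passed camera, and the Elongator list newly passed, downward (adjusted p = 0.0250). Mitochondrial respiration in spt5ΔCTR (0.000816) and the RNA polymerase II list in spt5-S1-15A (0.0262) also still passed with that term. The spt5-S1-15A list was lost (0) with both libraries apart, with these and a replicate block together, and with the sequencing set as a block, and with the set spt5Δ5 had 1 list, none of the 3 first called. The 84 genes shared by spt5Δ5 and spt5ΔCTR became 33 by DESeq2, 19 with mating type, 5 by reads, 50 with the centromere term, 28 beyond 50 kb, 40 with the sequencing set and 41 after thinning.

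Without single libraries the gene counts ranged from 297 to 663, 29 to 127, 0 to 31, 0 to 33, 7 to 124 and 69 to 290, in the order above. Shared genes ranged from 25 to 87, bins from 448 to 1205, 18 to 67 and 0 to 29, and lists from 0 to 3, 1 to 1 and 0 to 2. The difference from WT in log10 total insertions ranged from -0.25 to 0.12 for spt5Δ5, -0.10 to 0.08 for spt5ΔCTR and -0.21 to -0.03 for spt5-S1-15A. In percent of essential control genes it ranged from -0.00447 to 0.00845, 0.00288 to 0.0168 and 0.0540 to 0.0644. Where spt5-S1-15A is 1 sample it is assumed to vary like the other groups. Depth was lowered by thinning, by taking first runs and by leaving out libraries. On simulated counts 100% of genes with 4-fold more insertions and 88% with 4-fold fewer were recovered in spt5Δ5, and 52% and 36% at 2-fold. The changed genes held at least 10 insertions on average, so these shares do not cover sparser genes.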

Other observations

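The depth test of the centromere pattern, the repeat of the reads test without 9 genes, the gene sets and all counts of other splits below were chosen after the results were seen. Several genes of sugar breakdown and protein folding held more insertions in spt5Δ5 than in WT. HXK2, a hexokinase (log2 fold change 1.24 ± 0.26, n = 3 and 3), PFK1, phosphofructokinase (1.33 ± 0.37), the heat shock factor gene HSF1 (1.61 ± 0.26), the small heat shock protein genes HSP26 (1.66 ± 0.33) and HSP42 (1.55 ± 0.42) and the chaperone gene SSE1 (2.02 ± 0.45) were higher. TDH1 and TDH3, SSA3 and SSA4, and HSC82 and HSP82 were higher too, but these are near-identical pairs whose reads can be shared. Members whose reads can be shared between copies or repeats were not all left out of the 2 sets tested next. Those sets were put together after the gene results were seen, so their p-values are no independent test. Without the genes that prompted the sets, glycolysis and fermentation (11 tested, 6 higher, 11 positive, median 1.18) had a camera adjusted p of 1.22e-05 (0.0399 with an estimated correlation), and stress and chaperone genes (13 tested, 8 higher, median 0.99) 2.85e-07 (0.0399). In spt5ΔCTR the medians were 0.59 (4.58e-05; 0.0399) and 0.56 (0.000412; 0.061). In spt5-S1-15A they were 0.15 (0.786) and 0.12 (0.061). The full stress and chaperone set of 17, which includes genes that prompted it, passed there (median 0.29; 0.00449; 0.00379 with the centromere term) but not with an estimated correlation (0.0802), while in spt5ΔCTR it did (0.0162).

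Gene sets of mitochondrial translation shifted down in both deletions with the preset correlation, and few members passed singly. Values are again without the genes that prompted the sets, and neither translation set passed with an estimated correlation; the full ribosomal protein set did in spt5ΔCTR (0.0456). Mitochondrial ribosomal protein genes had a median of -0.89 in spt5Δ5 (38 tested, 4 lower, 37 negative; adjusted p = 2.12e-08; 0.0678 with an estimated correlation) and -0.87 in spt5ΔCTR (3 lower; 5.34e-10; 0.061). Mitochondrial aminoacyl-tRNA synthetase genes had a median of -0.70 (11 tested, 2 lower; 0.00214; 0.21) and -1.48 (2 lower; 1.13e-07; 0.061), with MSE1 at -1.37 ± 0.39 and -1.98 ± 0.43. ESCRT genes, which sort membrane proteins, had medians of -0.99 (0.0201; 0.0828) and -0.97 (0.000518; 0.0452), but the full set no longer passed with the centromere term in either (0.478 and 0.0613). Coenzyme Q genes had -0.55 (0.108; 0.21) and -0.26 (0.0201; 0.0828), with COQ8 at -1.74 ± 0.44 and -2.09 ± 0.47. The full set of 8 had -1.09 (0.00352; 0.0572) and -0.75 (2.54e-05; 0.0257), but includes genes that prompted it. Autophagy genes did not pass in either (0.349 and 0.106) but did in spt5-S1-15A (median 0.82; 0.0371; 0.398 with an estimated correlation and 0.0681 with the centromere term). These were 21 tests adjusted together.

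The gain in 20 glycolytic and stress genes called in spt5Δ5 was weighed. Sequencing set stays open. With the set as a block the median log2 fold change was 1.41, against 1.58, but only 1 spt5Δ5 library shares a set with WT, so that value rests on it. More insertions in strongly transcribed genes in general stay open: 85 ribosomal protein genes, tested for it, had a median of 0.21, which decides nothing. If cells carrying these insertions grew better, each position should also gain reads: the median log2 ratio of reads per position was 0.62, above the 95th percentile of 10000 random sets (0.23). Without the 9 genes that can share reads between copies or repeats it was 0.62 for 11 genes, against 0.35. These values go with a growth advantage, which may be a property of spt5Δ5 cells, but do not decide for it. The 20 genes were picked for their gain in positions, while the random sets came from all genes and were not matched for it. Large clones that yield extra called positions were not tested for.

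Fewer positions near centromeres in spt5Δ5 were weighed as well. Depth is argued against, since the highest share within 2 kb in spt5Δ5 was 1.83%, below all WT libraries, although spt5Δ5 held both the deepest library and the shallowest. Sequencing set stays open. The difference between genes within 50 kb and farther genes was -0.70 with the set as a block and -0.59 without, negative on 16 of 16 chromosomes, but the blocked value rests on 1 spt5Δ5 library. For spt5ΔCTR it went from -0.24 to -0.07 and for spt5-S1-15A from -0.40 to 0.03, so there the set and the strain stay open too. The blocked spt5ΔCTR value rests on 1 WT run. The set of spt5-S1-15A holds no WT run, so its blocked value is reached only through spt5ΔCTR replicate 1. The transposon starts on a centromeric plasmid, and a change in where it lands in spt5Δ5 may add to this pattern; that was not tested.

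For spt5Δ5 against WT, 1 of 10 splits of the 6 libraries gave as many genes (617 in the real split, 0 in the highest other). For spt5ΔCTR it was 1 of 10 (135; highest other 0) and for spt5Δ5 against spt5ΔCTR 1 of 10 (17; highest other 2), all too few for a share under 0.05. For all mutants against WT 1 of 100 drawn splits did (118, highest other 29), which argues at that share against a grouping by chance alone. Splits cannot tell genotype from strain, mating type or sequencing set, which are not balanced between WT and the mutants.

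Mitochondrial positions per 100000 were 30.1, 27.6 and 19.7 in spt5Δ5, 75.6, 31.0 and 28.1 in spt5ΔCTR, 78.7 and 74.7 in spt5-S1-15A and 53.4, 75.0 and 72.5 in WT. SWD2 positions in 5 equal parts of the gene, from 5-prime to 3-prime, were 2, 0, 1, 1 and 1 in WT, 7, 19, 14, 10 and 10 in spt5Δ5 and 6, 11, 14, 6 and 2 in spt5ΔCTR.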
